A study of Macaca fascicularis with 195 samples.

How the data were processed

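The series holds 195 samples, each a library of 1 cell, made with SC3-seq from cynomolgus monkey embryos and embryonic stem cell lines. SC3-seq amplifies cDNA by PCR and reads the 3′ ends of transcripts, so a long and a short transcript give about the same number of reads. Each cell came with a table of counts and a table of RPM. The count tables were deposited by the authors as whole reads per gene without normalization, per the file headers. The RPM tables were deposited by the authors as reads scaled to a fixed total, and their values summed to between 999429 and 999989 per cell. Per the submitters' processing notes, cutadapt 1.3, TopHat 1.4.1, Cufflinks 2.2.0 and HTSeq were used, with HTSeq 0.11.0 named for 88 samples and no HTSeq version for the other 107. The notes give these tools without roles. The genome build, the annotation, the treatment of reads that map to several places and the strand used for counting are not given in the sources used here. Where close copies of a gene exist, or a gene overlaps one on the other strand, its count is therefore uncertain. Across genes, counts and RPM correlated within each cell at r of 0.983 to 0.993 (median 0.99), and genes are not independent replicates. Of 26376 listed genes, 153 had no count in any cell. They were left out, and they held a median of 0.6% of the RPM.

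Groups were taken from the labels, which give the embryonic day or the line and name no animal, embryo or culture. Cells are not replicates of a condition, so each of the 9 groups was treated as 1 sample, with no test between groups and no p-value. The sex of embryos and lines is not in the labels and was not inferred. The 15 library labels (MS numbers) in the sample titles were read as batches of libraries, which no other label states. The 8 SOLiD cells of CMK9 were kept apart from NextSeq cells in all comparisons of lines, and TSIX is given for both, beside their sum. Every cell passed the filters of at least 100000 gene counts and 2000 genes with a read. Each sample was 1 picked cell, and no doublet caller was run.

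Genes were placed on chromosomes by matching gene identifiers to a RefSeq gene table of the assembly T2T-MFA8v1.1. Since the build behind the files is not given in the sources used here, no coordinates were taken from it. Of the 26376 identifiers 20464 matched, and they held a median of 97.8% of the counts. Of 8481 genes with a mean of at least 10 CPM, 8308 matched. The X chromosome had 828 genes, and 4 genes that matched Y alone were kept out of the ratios. TSIX, TMSB4X, SOX2 and DPPA4 did not match, so they entered no chromosome set.

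CPM was computed from the deposited counts as reads of a gene scaled to counts per 1000000 gene counts of the cell or of the summed cells. The X:A ratio of a cell was the mean CPM of X-linked genes over that of autosomal genes. Its genes had a mean of at least 10 CPM over NextSeq cells, and the 5% with the highest mean were left out. Cells were clustered with the Leiden method (scanpy 1.11.5, leidenalg 0.10.2) on 20 principal components of log2(CPM + 1) of 2000 variable genes, with 10 neighbours and resolution 1. X-linked and Y-linked genes were left out of clustering, and SOLiD cells of the choice of genes. The first components held 27.9% and 10.7% of the variance. Clusters were named from lists of fixed markers, and a class was compared between stages where it had at least 5 cells at each (3 for E16). Cluster 7 was kept under its number after its single library label was seen.

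For each comparison, counts were summed over the cells of a side and expressed as log2((CPM + 5)/(CPM + 5)), and folds are ratios of CPM. A gene counted as measured with at least 20 CPM on a side. Counts and medians of lists, of X-linked and autosomal genes and of chromosomes use all measured genes, also those carried by few cells. A gene could be named if it also had a read in at least 50% of the cells of the higher side. Among genes that could be named, the text names the 10 largest and 10 smallest ratios and the 5 largest and 5 smallest of X-linked genes. From each of 26 gene lists it names the 2 to 4 such members with the largest absolute ratio. Of these, the paragraphs give examples. XIST was to be reported always, but no gene in the tables has that name, and TSIX took its place after this was seen. Genes that lead a cluster were not named in comparisons of classes, or of the lines with E13, that held cells of that cluster. They stayed in the counts and medians of lists: MIXL1 of the streak list and SFRP2 of the post-implantation list, for example, led cluster 3. The single genes given for lone cells, for the 2 E13 cells of cluster 4 and for cluster 6 fall outside the rule and were chosen after their values were seen. A gene with no count on a side was set at a floor of 3 counts over the group, which makes its fold a lower bound. A list or the X chromosome was described by the percentile of its median among 10000 random autosomal lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these libraries and is no test between conditions.

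Sums carry exact 95% Poisson intervals and shares of cells exact binomial (Clopper-Pearson) intervals. Reads made by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only and not the spread between embryos. For shares of cells with a read, cells were thinned to 200000 counts. Deeper libraries give narrower intervals: the cells ranged from 214729 to 4746935 counts.

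The procedure was tested on simulated data for E08 and E13 cells, with counts drawn for 26223 genes. Of 50 genes raised 2-fold, 50 came within 1 log2 unit (median 0.99), of 50 raised 4-fold 50 (median 1.9), of 50 at 0.5-fold 50 (median -0.96) and of 50 at 0.25-fold 49 (median -1.69). With X-linked genes left alone, their median lay at percentile 12.8 (187 X-linked genes) and the X:A ratio between the stages was 1.0. With X-linked genes raised 1.5-fold, the percentile was 100 and the recovered ratio of X:A 1.51. All simulated cells of a stage were drawn from 1 profile, without library labels, embryos or cell classes, so the simulation does not cover differences between these.

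The alternatives tried were TMM scaling (edgeR 4.0.16), size factors (DESeq2 1.42.0), means of per-cell CPM, 1 or 20 CPM added, CPM minima of 1, 50 or none, resolutions 0.5 and 2, the RPM values, medians over genes, other X-linked gene sets, thinning to 100000 counts or none, and at least 3 reads for a share. In comparisons, each library label with at least 3 but not all cells of a side was also left out in turn, as was each CMK6 cell. Both packages gave scaling factors only, and no count test was run. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 were used. Of the fixed lists, all Y-linked genes, XIST, JPX, FTX, XACT, LDHA, H19, IGF2, MEG3, GNAS, HSPA1A and HSPA1B are not analysed here.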

Results

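The data were single-cell transcriptomes of cynomolgus monkey embryos and of 2 cynomolgus embryonic stem cell lines, made with SC3-seq, a single-cell RNA-seq method that reads the 3′ ends of transcripts. The labels placed 195 cells in 9 groups. These were embryonic stages E06 (1 cell), E07 (84 cells), E08 (49 cells), E09 (1 cell), E13 (40 cells), E16 (6 cells) and E51 (1 cell), and the lines CMK6 (3 cells) and CMK9 (10 cells). Per the labels' protocols, whole embryos were dissociated with trypsin before implantation, whereas after implantation an embryonic part was taken out of the implantation site. The lines grew on mouse feeder cells with LIF and bFGF. A cell held between 214729 and 4746935 gene counts, with a median of 1052908. The median depth was 935927 counts in E07, 832332 in E08, 1632241 in E13, 884147 in E16, 794055 in CMK6 and 1372772 in CMK9. The median number of genes with a read was 9933 in E07, 10390 in E08, 7954 in E13, 7665 in E16, 9913 in CMK6 and 10145 in CMK9. The labels name no animal, embryo or culture, so each group counts as 1 sample, and no test or p-value is given for any comparison between groups.

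The embryo cells fell into classes that were named from marker genes fixed before the data were examined. Epiblast-like cells, the pluripotent lineage that forms the embryo proper, numbered 28 in E07, 22 in E08, 38 in E13 and 6 in E16. Hypoblast-like cells, the primitive endoderm that lines the yolk sac, numbered 26 in E07 and 10 in E08. Most E07 epiblast-like cells were in cluster 0 (21 of 28), most of those of E08 in cluster 1 (20 of 22), and all of those of E13 and E16 in cluster 3. The single E06 cell fell in cluster 0, the E09 cell in cluster 2 and the E51 cell in cluster 3. They entered no comparison of classes, and the E51 cell had germ cell transcripts that were low in the epiblast-like cells of E13. Cluster 6 held 30 E07 cells and 1 E08 cell, with trophoblast and hypoblast markers, and was left unnamed. At resolution 2 it split into 14 cells with 18 of 22 trophoblast markers detected, led by GATA2, and 17 cells with 9 of 22. Cluster 7 held 16 E08 cells, all of 1 library label, with 18 of 27 hypoblast markers detected. Cluster 4 held the 13 cells of the lines and 2 E13 cells and was led by mesenchyme genes such as HGF, VIM and COL3A1. Clusters 4, 6 and 7 were kept out of the classes, cluster 7 after its single library label was seen.

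The series is about X-chromosome dosage compensation, and the X:A ratio asks how far X-linked genes are expressed at the level of autosomal genes. The median ratio was lower in E07 and E08 than in E13 and E16. Since the level of the ratio depended on the genes that entered it, it is read between stages and not against 1. The median X:A ratio over cells was 0.628 in E07 (quartiles 0.54 and 0.899) and 0.702 in E08 (0.596 and 0.825). It was 0.979 in E13 (0.844 and 1.049) and 1.026 in E16 (0.9 and 1.189). In epiblast-like cells the medians were 0.576 in E07, 0.627 in E08, 0.987 in E13 and 1.026 in E16. In hypoblast-like cells they were 0.679 in E07 and 0.614 in E08. The unnamed cluster 6 had a median of 0.628 in its E07 cells, and cluster 7 had 0.833 in its E08 cells. Cells within a stage spread widely, from 0.358 to 1.202 in E07, from 0.418 to 1.101 in E08 and from 0.544 to 1.555 in E13. Within label MS257 of E07, replicates 28 to 48 ranged from 0.763 to 1.202 and replicates 50 to 75 from 0.484 to 0.663. The first of these runs lay around the E13 median of 0.979, so the E07 median does not describe all cells of the stage. Whether such runs are separate embryos or sexes is not in the labels and was not tested. The 6 E08 epiblast-like cells of label MS273, which held all of cluster 7, had a median of 0.838, so the ratio of cluster 7 cannot be told apart from that of its label. The lone cells had ratios of 0.921 in E06, 0.413 in E09 and 1.089 in E51.

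Among the cell lines, CMK6 had a median X:A ratio of 0.928 (range 0.872 to 0.934). CMK9 had 0.992 in its 2 NextSeq cells and 1.508 in its 8 SOLiD cells, which were made under another library label. The ratio used 249 X-linked and 7639 autosomal genes. With a minimum of 50 CPM the medians were 0.887 in E08 and 1.279 in E13. Library labels, the MS numbers in the sample titles, were read as groups of libraries made together, although no other label describes them. Their ratios differed: E08 cells of label MS273 had 0.84, those of MS219 0.601 and those of MS130 0.635. The E13 labels with at least 3 cells lay between 0.977 and 1.035. Those with 1 or 2 cells stood at 0.691 (MS130), 0.854 (MS133), 0.872 (MS173), 0.875 (MS132) and 1.013 (MS083). Of these, MS130, MS132 and MS173 also held E08 cells.

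**Figure D1:**
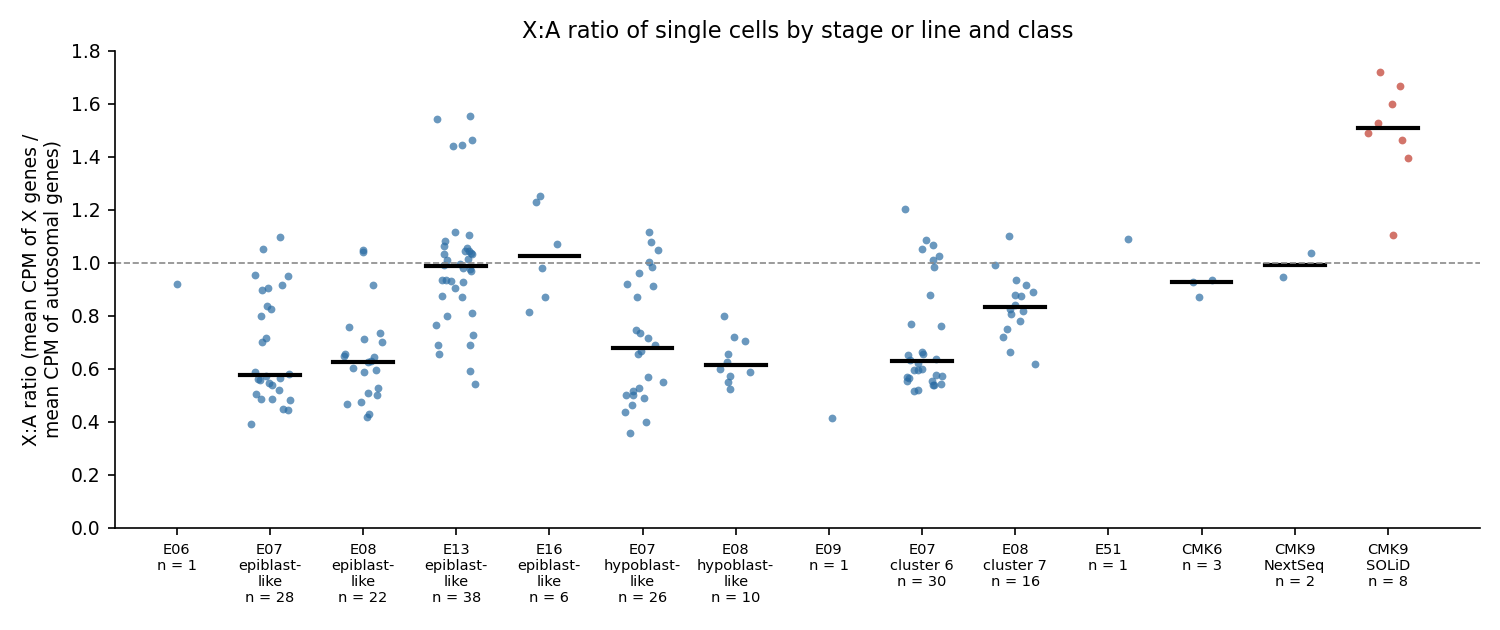
X:A ratio (mean CPM of 249 X-linked genes over mean CPM of 7639 autosomal genes, vertical axis) of each cell, by stage or line and class (horizontal axis). Each point is 1 cell, the black bar is the median of groups with more than 1 cell, the dashed line marks equal means, and SOLiD cells are red. Epiblast-like medians are 0.576 in E07, 0.627 in E08, 0.987 in E13 and 1.026 in E16. The E08 cell of cluster 6 and the 2 E13 cells of cluster 4 are not drawn.

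Between E08 and E13, that is before against after implantation, X-linked genes as a set were higher in the E13 epiblast-like cells. The median log2 ratio (E13 over E08) of the measured X-linked genes exceeded that of 6783 autosomal genes by 0.46, which is 1.37-fold. That lay at percentile 100 of matched autosomal lists, whose central range was -0.17 to 0.1. Of the X-linked genes 69.1% lay above the autosomal median, 61 were at least 2-fold higher in E13 and 13 at least 2-fold lower. Taken one by one, the 20 autosomes ranged from -0.145 (chromosome 16) to 0.181 (chromosome 8), against 0.455 for X. Both the list of human genes subject to X inactivation (63 of 107 measured members higher, median 0.31, percentile 100) and the list of human escape genes (14 of 19 higher, median 0.43, percentile 99.1) were higher in E13. The E08 cells compared were mainly of cluster 1 and the E13 cells all of cluster 3. The 3 library labels that held epiblast-like cells of both stages gave 9 E08 and 3 E13 cells. Summed over these labels the difference was 0.24, with the inactivated list at -0.02, and over MS130 and MS173 alone 0.34. The shares of the labels differed between the sides, so label was not held constant. With no CPM minimum, which adds many genes near 0 on both sides, the difference over all epiblast-like cells was 0.0.

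**Figure D2:**
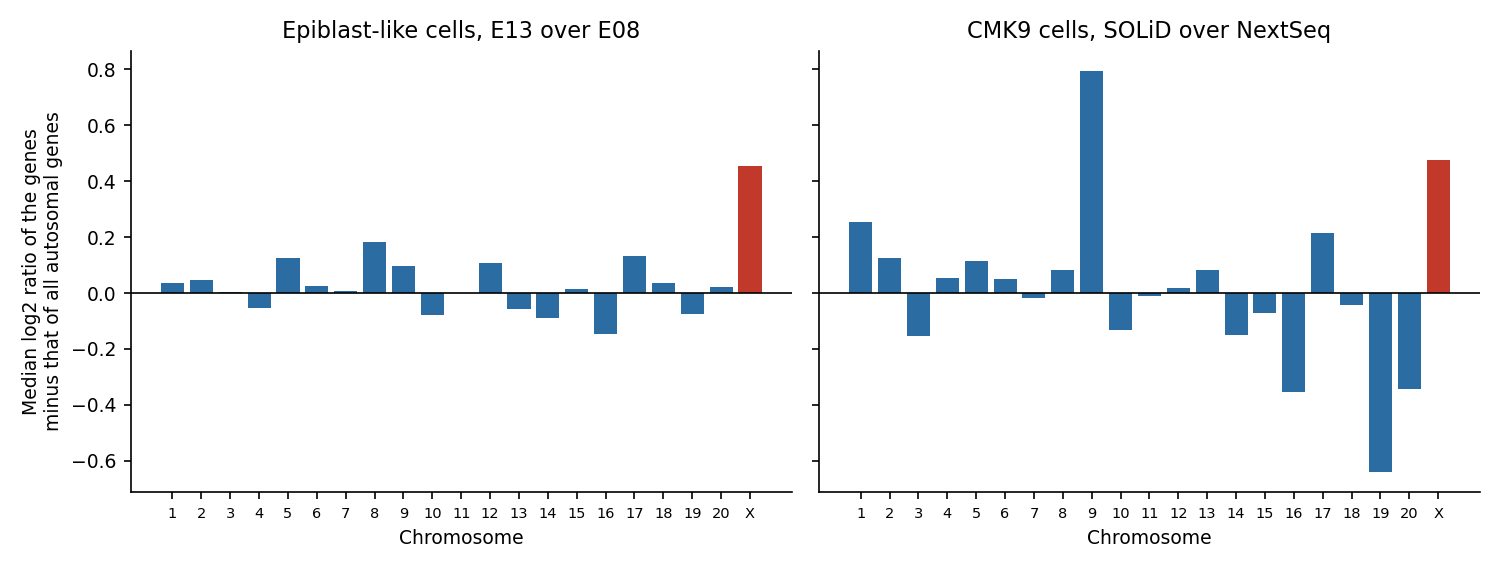
Median log2 ratio of the measured genes of each chromosome minus that of all autosomal genes (vertical axis), for the autosomes in blue and X in red (horizontal axis). In epiblast-like cells, E13 over E08, X stands at 0.455 and the highest autosome at 0.181. In CMK9 cells, SOLiD over NextSeq, X stands at 0.477, below chromosome 9 (0.795) and above the other autosomes.

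Single X-linked genes, named for the size of their ratios among X-linked genes or within their lists, differed in both directions. They are examples and add no support to the difference of the set. SLC16A2, a thyroid hormone transporter next to the X inactivation centre, was 26.5-fold higher in E13 (132.1 against 5.0 CPM). SMARCA1, a chromatin remodeller, was 21-fold higher, and AP1S2, an adaptor subunit of vesicle coats, 13.2-fold higher (502.1 against 38.1 CPM). The synaptic adhesion gene NLGN4X stood at 104.8 CPM in E13 and 1.2 CPM in E08. Among escape genes, MED14 stood at 112.2 against 28.4 CPM, USP9X at 328.6 against 135.7 CPM and the histone demethylase KDM6A at 105.9 against 43.6 CPM. Against the set, BRWD3 was 9.22-fold lower in E13 and the polyamine enzyme gene SAT1 5.64-fold lower (35.5 against 200.3 CPM). TMSB4X, which binds actin monomers, stood at 26.7 against 335.4 CPM. All 3 measured genes of the X inactivation centre were higher in E13 (median 0.89, percentile 94.4), among them RLIM at 47.3 against 23.3 CPM and CHIC1 at 34.3 against 19.5 CPM. Of 3 measured pseudoautosomal genes 2 were higher (median 0.71, percentile 90.5), with ZBED1 at 28.6 against 15.6 CPM. The list of X-linked MAGE, GAGE and stem cell genes had 2 measured members, ZIC3 higher (67.1 against 34.5 CPM) and HTATSF1 lower (95.1 against 122.8 CPM). No member of the Y-linked list was measured.

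Outside X, epiblast genes of the stage before implantation were lower in the E13 epiblast-like cells and those of the stage after it higher. All 8 measured pre-implantation epiblast markers were lower in E13, with a median log2 ratio of -3.32 (percentile 0.0). They included DNMT3L, a cofactor of DNA methylation (17.6 against 490.9 CPM, 28-fold), the maternal-effect gene DPPA3 (19 against 315.0 CPM) and the transcription factor TFCP2L1 (4.1 against 95.7 CPM). All 13 measured post-implantation epiblast markers were higher (median 1.48, percentile 100). SFRP1, a secreted WNT antagonist, stood at 1021 against 8.7 CPM (118-fold), FGF2 at 118.3 against 3.5 CPM (33.5-fold) and SOX11 at 73.1 against 0.8 CPM. Core pluripotency genes were mixed (4 of 12 higher, median -0.36, percentile 10.2): NANOG stood at 650.2 against 1727 CPM and DPPA2 at 110.9 against 1265 CPM, whereas LIN28A stood at 1731 against 1023 CPM. Among the genes with the largest ratios, the surface glycoprotein CD24 was 47.4-fold higher (2572 against 54.3 CPM) and the matrix proteoglycan VCAN 108-fold higher. The aminopeptidase gene ANPEP was 709-fold lower (1.0 against 687.4 CPM), and NLRP7, a maternal-effect gene of imprinting, 62.2-fold lower (47.2 against 2933 CPM).

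Trophoblast markers were also lower in E13 (8 of 8, median -3.25, percentile 0.0), among them the keratins KRT18 (62.7 against 2008 CPM) and KRT8 (61.8 against 981.6 CPM). Germ cell markers were lower in 5 of 6 members (median -3.42, percentile 0.0), with SOX15 at 3.6 against 178.8 CPM. Primitive streak and mesoderm genes were higher in 5 of 7 (median 2.16, percentile 100), with the activin inhibitor FST at 75.6 against 3.4 CPM and CDX1 lower at 9.8 against 55.2 CPM. Without the E13 cells of label MS127 that list's median was -1.85. Hypoblast and yolk sac endoderm markers showed no common direction (3 of 5 higher, median 0.29, percentile 73.7). Extraembryonic mesenchyme markers were higher in 3 of 4 (median 1.32, percentile 99.3), with COL1A1 at 168.8 against 24.7 CPM. Of 4 amnion markers 3 were lower (median -0.96, percentile 8.31), and IGFBP3 was higher (93.7 against 5.3 CPM). Feeder-type fibroblast genes were higher in 3 of 3 (median 1.13, percentile 98.4). Of the blood and endothelium list 1 gene was higher and CDH5 lower (2.6 against 27 CPM), and of the endometrium list only SPP1 was measured, at 198.4 against 196.3 CPM.

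Glycolysis genes were higher in 10 of 15 (median 0.36, percentile 96.6), with TPI1 at 659.8 against 179.1 CPM, PKM at 403.7 against 128.3 CPM and the X-linked PGK1 at 1667 against 676.6 CPM. Mitochondrial respiration genes were lower in 9 of 9 (median -0.41, percentile 13.4), with NDUFA1 at 128.4 against 435.4 CPM. Ribosomal protein genes were higher in 16 of 20 (median 0.4, percentile 99.6), with RPL13 at 2398 against 1063 CPM and RPL10 at 4528 against 2022 CPM. X inactivation and Polycomb factors were higher in 13 of 23 (median 0.18, percentile 89.3), and the maintenance methyltransferase DNMT1 stood at 163.4 against 36 CPM and DNMT3B at 3781 against 1353 CPM. Imprinted genes split evenly (3 higher, 3 lower, median 0.13, percentile 70.9), with SNRPN 3.93-fold higher at 660.9 CPM. Cell cycle genes were higher in 6 of 15 (median -0.21, percentile 27.7), with the cyclin CCND2 at 76.5 against 7.9 CPM and CCND3 at 26.8 against 87.9 CPM. Signalling genes of the FGF, TGF-beta and WNT pathways were lower in 11 of 16 (median -0.59, percentile 1.54), with NODAL at 36.4 against 154.4 CPM and FGFR2 higher at 66.8 against 9.4 CPM. Stress and immediate early genes were lower in 6 of 7 (median -1.2, percentile 0.41), with FOS at 17.4 against 124.5 CPM.

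Counting error was small beside these differences: for the 105 named genes of this comparison the 95% Poisson interval of values of at least 20 CPM had a median half-width of 2.76% of the value and reached 9.36%. The values of the 3 labels with at least 3 cells on each side did not overlap for 85 of the 105 genes. Chance gives 10.0% for genes not chosen by their ratios, but these were named for their size, so the shares are not comparable. No label held at least 3 cells of both stages, so label and stage cannot be told apart in these values. TMM scaling moved the median of all genes by 0.11 on the log2 scale.

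**Figure D3:**
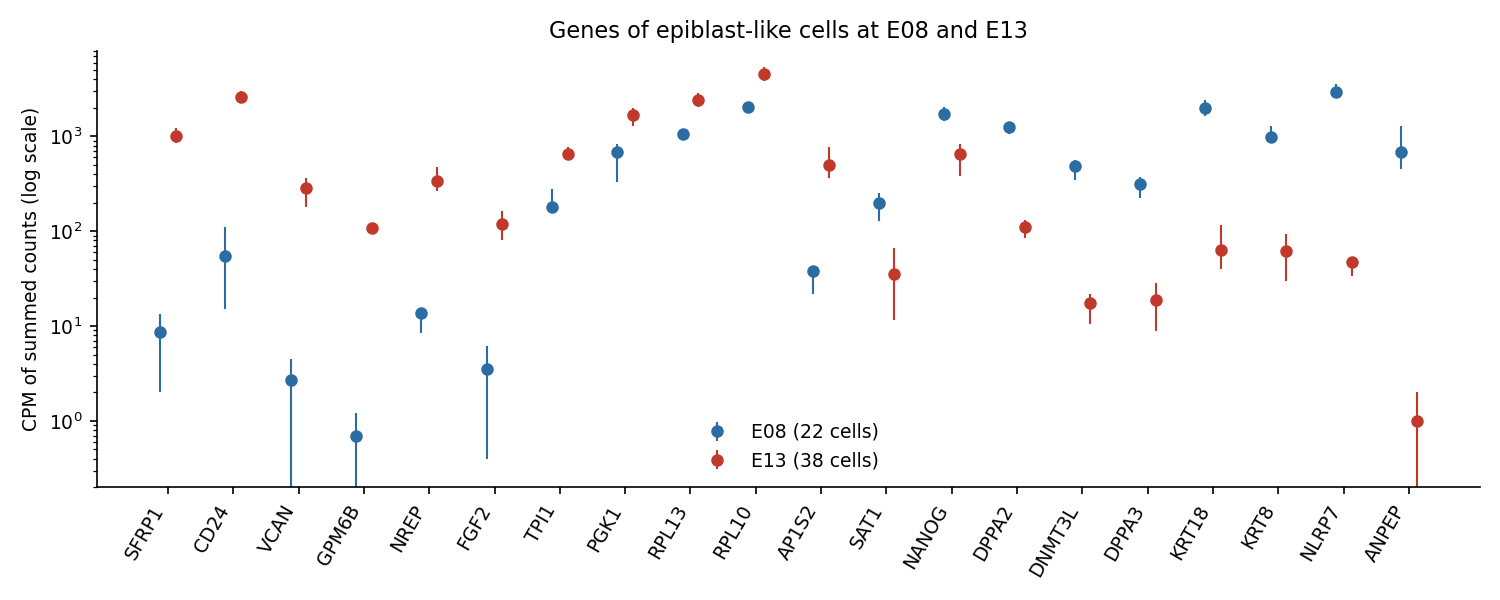
CPM of counts summed over epiblast-like cells (vertical axis, log scale) for 20 named genes (horizontal axis) at E08 (blue, 22 cells) and E13 (red, 38 cells). Vertical lines span the values of the 3 library labels with at least 3 cells on each side, and those that reach 0 run off the axis. SFRP1 stands at 8.7 CPM in E08 and 1021 CPM in E13, and KRT18 at 2008 and 62.7 CPM.

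Between E07 and E08, on consecutive days before implantation, the X-linked difference of epiblast-like cells was small and its sign depended on library labels. The measured X-linked genes differed from 6283 autosomal genes by -0.04 (E08 over E07, percentile 10.3), a value that was 0.18 without the E07 cells of label MS257 and -0.13 without the E08 cells of label MS273. All 5 measured post-implantation epiblast markers were already higher in E08 (median 1.13, percentile 100): SALL2 stood at 95 against 14.9 CPM (6.36-fold), the WNT receptor FZD7 at 104.9 against 30.9 CPM and ZIC2 at 113.2 against 48.9 CPM. SPARC, a matrix glycoprotein, was 4.45-fold higher (928.8 against 208.6 CPM), and of the targets of BMP signalling ID2 stood at 108.8 against 9.6 CPM and ID3 was 5.91-fold higher at 236.7 CPM. Core pluripotency genes were mixed (5 of 12 higher, median -0.13, percentile 6.46), with NANOG at 1727 against 1020 CPM and SOX2 at 260.3 against 126.4 CPM. Hypoblast markers were lower in 5 of 6 (median -0.49, percentile 0.33), among them HNF4A at 15.2 against 38.9 CPM, and GATA6, the hypoblast regulator, at 1.4 against 20.7 CPM. Among the lowest genes, the stress-response gene HERPUD1 stood at 10.5 against 66.5 CPM and the mitochondrial topoisomerase TOP1MT at 34.1 against 157.4 CPM.

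Smaller lists went both ways. Pre-implantation markers were lower in 6 of 10 (median -0.16, percentile 12.2), with ESRRB at 9.2 against 30.4 CPM, and trophoblast markers split evenly (5 of 10, median -0.06, percentile 29). Among X-linked genes, human escape genes were lower in 15 of 19 (median -0.22, percentile 0.65), with ALG13 at 76.9 against 124.2 CPM and GEMIN8 at 25 against 45.7 CPM, while inactivated genes split 44 to 50 (median -0.05, percentile 12.1). SLC7A3, an amino acid transporter, stood at 59.9 against 15.6 CPM, SAT1 at 200.3 against 72.1 CPM and DIAPH2 at 7.8 against 26.5 CPM. Respiration genes were lower in 8 of 9 (median -0.23, percentile 2.07), with NDUFA4 at 565.3 against 1155 CPM, and imprinted genes in 5 of 6 (median -0.36, percentile 1.29). Cell cycle genes were higher in 11 of 14 (median 0.15, percentile 93.6), and the inhibitor CDKN1A was lower (9.1 against 35.2 CPM). Stress and immediate early genes were higher in 6 of 8 (median 0.47, percentile 99.8), with FOS at 124.5 against 55.9 CPM; without the E08 cells of label MS219 the list's median was -0.79 and FOS was lower by the same amount. No library label held at least 3 cells of both stages, so label and stage cannot be told apart here. Label values did not overlap for 39 of 99 named genes. Chance gives 20.0% for genes not chosen by their ratios, but these were named for their size, so the 2 shares are not comparable.

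Hypoblast-like cells of the same days differed in genes of the primitive streak and of mesenchyme, which were higher in E08, though MIXL1, EOMES, GSC, VIM and DKK4 were not clearly higher once the cells of 1 library label were left out. All 10 E08 cells were in cluster 2, with 18 of the 26 E07 cells, and the other 8 E07 cells were in cluster 5. At resolution 2 the stages shared no cluster, and DKK4 led the cluster of the E08 cells. The streak list was higher in 5 of 6 members (median 3.49, percentile 100): MIXL1 stood at 345.0 against 7.1 CPM (48.9-fold), EOMES at 163.6 against 11.2 CPM and GSC, an organiser gene, at 212.8 against 32.5 CPM. The intermediate filament gene VIM was 79.5-fold higher (93 against 1.2 CPM), VCAN 97.2-fold higher, and mesenchyme markers were higher in 3 of 4 (median 2.41, percentile 100). DKK4, a WNT inhibitor, stood at 468.4 CPM in E08 with no count in E07, at least 4800-fold higher against a floor of 3 counts over the group. SYT13 stood at 89.9 CPM in E07 with no count in E08 (at least 255-fold lower), and the neuropeptide NPY was 17.1-fold lower. Hypoblast markers themselves were lower in 15 of 19 (median -0.25, percentile 0.87), as with HNF4A at 146.9 against 229.5 CPM and APOC3 at 37.5 against 72.1 CPM, whereas fibronectin FN1 stood at 3847 against 2118 CPM.

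Cell cycle genes were lower in 10 of 13 in the E08 hypoblast-like cells (median -0.41, percentile 0.09), with TOP2A at 200.6 against 748.3 CPM and CCNB1 at 128.3 against 386.6 CPM. Stress and immediate early genes were higher in 7 of 7 (median 1.19, percentile 100), with EGR1 at 139.5 against 30.8 CPM, and trophoblast markers in 7 of 10 (median 0.61, percentile 99.9). Post-implantation epiblast genes were higher in 5 of 6 (median 0.8, percentile 100), with ZIC2 at 147.8 against 8.9 CPM, and signalling genes in 8 of 14 (median 0.36, percentile 99.2), with LEFTY1 at 321.0 against 40.7 CPM. The 188 X-linked genes differed from 6547 autosomal genes by -0.08 (percentile 0.92, matched range -0.03 to 0.13). Human escape genes were lower in 18 of 20 (median -0.37, percentile 0.04), as with TXLNG at 26.2 against 59.4 CPM and EIF1AX at 296.8 against 456.5 CPM, and inactivated genes in 51 of 99 (median -0.02, percentile 15.9). ZIC3 stood at 82.5 against 9.2 CPM and ATP11C at 35.2 against 104.5 CPM. The E08 side rested on 10 cells, 8 of them of label MS219; without these 8 the log2 ratios of MIXL1, EOMES and DKK4 were 0.03, 0.0 and 0.0, the medians of the post-implantation and signalling lists -0.66 and -0.7 and the X-linked difference -0.24, and ZIC2, GSC, LEFTY1 and VIM were lower than in E07. Without the E07 cells of label MS252 the X-linked difference was -0.18. With the 16 cells of cluster 7 counted as hypoblast-like, the X-linked difference was 0.13 and the median of the escape list 0.1. Leaving these cells out and counting them in were both choices made after seeing the data, so the sign of the X-linked difference rests on such a choice.

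Between E13 and E16, after implantation, X-linked genes did not stand apart from autosomal genes in sums over epiblast-like cells. The 245 X-linked genes differed from 7023 autosomal genes by 0.0 (percentile 44), but with means of per-cell CPM by 0.14 (percentile 98.4). In the sums 49 X-linked genes were at least 2-fold higher in E16 and 36 at least 2-fold lower. Primitive streak and mesoderm genes were higher in E16 in 10 of 11 (median 2.37, percentile 100): EOMES was 10.1-fold higher (415.8 against 41.2 CPM), FST stood at 256.5 against 75.6 CPM and WNT3 stood at 35.3 against 2.8 CPM. At resolution 2, 5 of 6 E16 cells but 12 of 38 E13 cells were in a cluster led by streak genes such as MIXL1 and EOMES, and within it the list's median was 1.28, a comparison chosen after seeing the data. Over all epiblast-like cells the list's median was also 1.28 with means of per-cell CPM. HAPLN1, a matrix link protein, was 29.1-fold higher and VIM 17.2-fold higher (565.2 against 32.8 CPM). Trophoblast markers were higher in 9 of 9 (median 2.13, percentile 100), with TFAP2C at 123.7 against 5.8 CPM and GATA3 at 46.5 against 6.8 CPM, and hypoblast markers in 8 of 9 (median 2.03, percentile 100), with the laminin LAMA1 at 95.3 against 9.1 CPM. Core pluripotency genes were lower in 10 of 12 (median -0.3, percentile 7.59), with PRDM14 at 31.5 against 135.3 CPM, while GDF3 stood at 321.0 against 99.1 CPM. Caveolin gene CAV1 was 24.1-fold lower (4.7 against 113.8 CPM) and the zinc transporter SLC30A1 21.7-fold lower.

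Signalling genes were higher in 15 of 20 in E16 (median 1.18, percentile 100), with ID2 4.32-fold higher at 259.6 CPM, and germ cell markers in 6 of 7 (median 2.57, percentile 100), with SOX15 at 39.4 against 3.6 CPM. Post-implantation epiblast genes split (8 of 14 higher, median 0.13), with OTX2 at 81 against 10.5 CPM and DNMT3B at 1479 against 3781 CPM. Imprinted genes were higher in 5 of 8 (median 1.02, percentile 99.4), with NDN at 81.7 against 19.6 CPM. Cell cycle genes (6 of 15 higher, median -0.28, percentile 7.86), ribosomal protein genes (10 of 20, median -0.02, percentile 65.9) and X inactivation and Polycomb factors (10 of 22, median -0.08, percentile 29.3) differed little. Among X-linked genes ALG13 was 10.6-fold lower (8.6 against 90.7 CPM), AMER1 stood at 41.8 against 2.6 CPM and SAT1 at 201.2 against 35.5 CPM. Escape genes were lower in 14 of 22 (median -0.29, percentile 6.33) and inactivated genes were higher in 60 of 115 (median 0.05, percentile 34.6), a median that was -0.06 with TMM scaling. Pre-implantation markers were higher in 4 of 6 (median 2.04), a median that was -0.04 without the E13 cells of label MS107. The E16 side held 6 cells, 4 of them of label MS173, and without those 4 the median of the mesenchyme list (2.7) was -2.82 and VIM was lower in E16. Leaving them out, here and in the comparison of whole stages, moved 39 log2 ratios of single genes and reversed 20, with 145 the same. It moved 11 list medians and reversed 1, with 32 the same, so the other values of E16 also depend on these cells. Within MS173 alone, with 4 E16 cells against 1 E13 cell, the X-linked difference was 0.31.

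**Figure D4:**
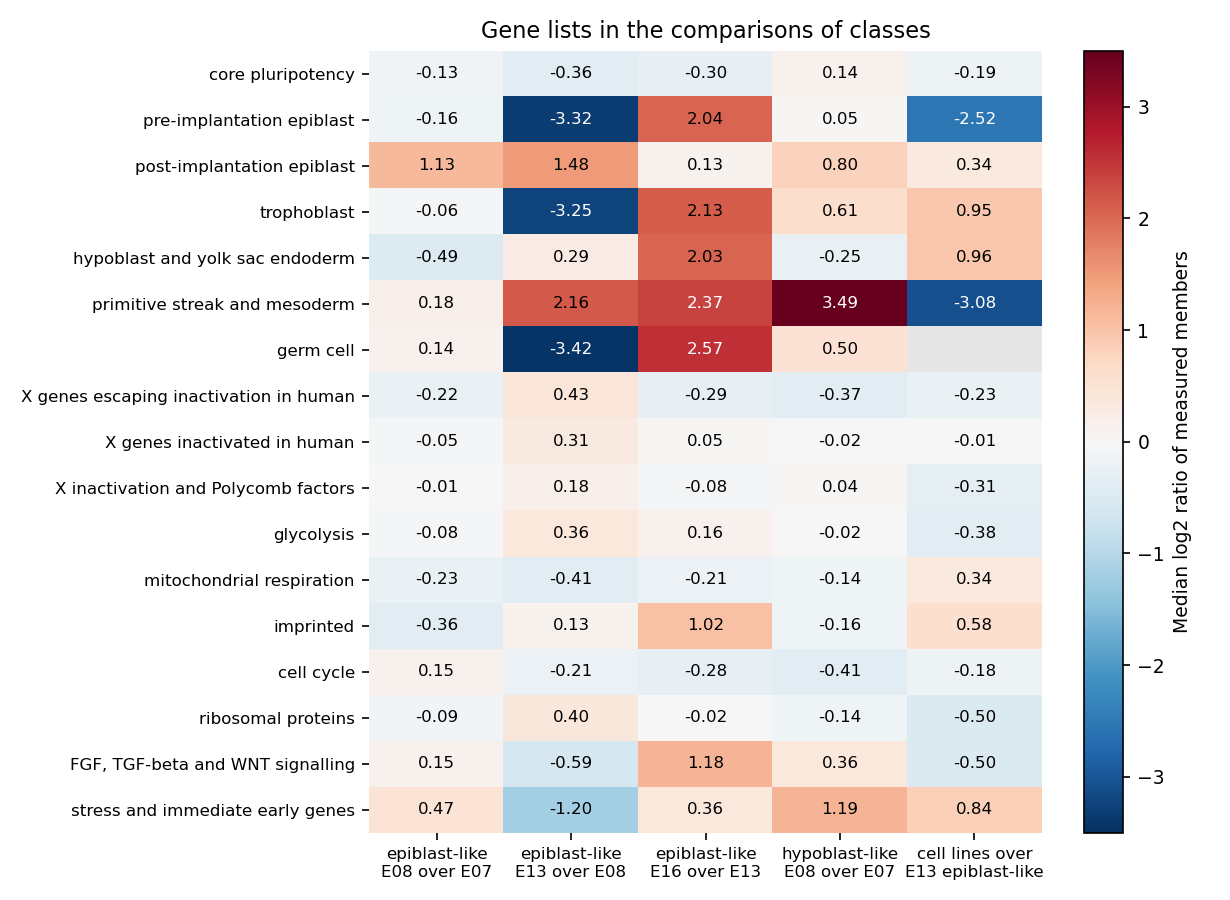
Median log2 ratio of the measured members of 17 gene lists (vertical axis) in 5 comparisons (horizontal axis), as number and colour, red for higher and blue for lower in the group named first. Grey marks a list with fewer than 3 measured members, and TMM scaling turns the sign of 3 values near 0, those of pre-implantation genes (-0.06) and Polycomb factors (-0.07) in hypoblast-like cells and of inactivated genes in E16 over E13 (-0.06). Pre-implantation epiblast genes stand at -3.32 in E13 over E08 and primitive streak genes at 2.16 there and 2.37 in E16 over E13.

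Whole stages, compared as labelled and without classes, mix cell types in different shares. All E13 cells against all E08 cells gave an X-linked difference of 0.34 (229 X-linked and 7001 autosomal genes, percentile 100), which was 0.55 without the E08 cells of label MS273 and 0.01 with no CPM minimum. E08 against E07 gave 0.04 (percentile 89, with -0.18 without the E08 cells of label MS273 and 0.23 without the E07 cells of MS257) and E16 against E13 gave 0.02 (percentile 57.9), or 0.16 (percentile 99.3) with means of per-cell CPM. Hypoblast markers were lower in E13 than in E08 in 15 of 16 (median -3.81, percentile 0.0), with the apolipoprotein APOA1 795-fold lower (2.5 against 1980 CPM) and the basement membrane gene NID2 88.2-fold lower (23 against 2031 CPM). No E13 cell was hypoblast-like, whereas the E08 sum held 10 hypoblast-like cells and the 16 cells of cluster 7, with 18 of 27 hypoblast markers detected. Pre-implantation epiblast markers were lower in 8 of 8 (median -3.71), and post-implantation markers higher in 12 of 14 (median 1.8), with SFRP2 at 372.4 against 6.4 CPM. In E08 against E07 the streak list was higher in 6 of 7 (median 1.73), with MIXL1 at 79.9 against 9.6 CPM, and the ectonucleotidase ENPP1 stood at 270.4 against 38.9 CPM. Without the E08 cells of label MS219 that median was 0.23 and the log2 ratio of MIXL1 0.05. ATP6V0D2 and PLAC8, which led cluster 6, stood at 0.4 against 23 CPM and 28.6 against 112.8 CPM. TMM scaling moved the median of all genes by -0.14 in E08 against E07 and by 0.17 in E13 against E08.

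The stem cell lines were compared with E13 epiblast-like cells, taking the 5 NextSeq cells of both lines together. X-linked genes did not stand apart (-0.01 against 6818 autosomal genes, percentile 47.1). Taken one by one, the autosomes ranged from -0.265 (chromosome 17) to 0.409 (chromosome 16), against -0.006 for X. Among the genes with the largest ratios, the small GTPase RHOB was 61.1-fold higher (375.4 against 6.1 CPM), AHNAK 42.5-fold higher, calponin CNN1 67.6-fold higher and the transcription factor EGR4, without a count in E13, at least 3020-fold higher. Stress and immediate early genes were higher in 6 of 8 (median 0.84, percentile 98.7), with GADD45A at 63.4 against 4.5 CPM, but the median was -0.09 without the CMK6 cells. DPPA5 stood at 6.9 against 954.1 CPM, and KHDC3L and NLRP2, which belong to the maternal complex of oocyte and early embryo, were 80.9-fold and 72.4-fold lower. Pre-implantation markers were lower in 3 of 3 (median -2.52, percentile 0.03), among them KLF4, at 23.7 CPM in E13 and without a count in the lines (at least 37.9-fold). Core pluripotency genes split (5 of 12 higher, median -0.19), with GDF3 at 7.3 against 99.1 CPM, NANOG at 229.0 against 650.2 CPM and SOX2 at 550.7 against 251.4 CPM. Primitive streak genes were lower in 4 of 5 (median -3.08, percentile 0.0), although FST stood at 241.7 against 75.6 CPM.

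Ribosomal protein genes were lower in the lines in 17 of 20 (median -0.5, percentile 0.09), with RPL13 at 1169 against 2398 CPM. Glycolysis genes were lower in 11 of 15 (median -0.38, percentile 1.83), with HK2 at 48.5 against 142.7 CPM, but the glucose transporter SLC2A3 stood at 2295 against 567.1 CPM. X inactivation and Polycomb factors were lower in 15 of 22 (median -0.31, percentile 1.73), including UHRF1 (33.3 against 79.8 CPM) and EZH2 (50.1 against 107.4 CPM). Imprinted genes were higher in 7 of 9 (median 0.58), with PEG10 at 50.3 against 9.4 CPM. Of the X-linked genes, TSPYL2 stood at 41.4 against 2.9 CPM, TMSB4X at 296.4 against 26.7 CPM, DIAPH2 at 15.4 against 91.4 CPM and KDM6A at 28.3 against 105.9 CPM. Escape genes were lower in 11 of 19 (median -0.23, percentile 5.9) and inactivated genes split 53 to 54 (median -0.01). Feeder-type fibroblast genes were higher in 3 of 4 (median 1.08, percentile 98.7), a list that holds TAGLN, one of the leading genes of the cluster of the lines, and COL1A1 stood at 281.4 against 168.8 CPM. Signalling genes were lower in 8 of 15 (median -0.5, percentile 0.61), a median that was 0.05 without the CMK6 cells and 0.18 with a minimum of 50 CPM. Hypoblast markers were higher in 4 of 7 (median 0.96, percentile 98.3) and trophoblast markers in 3 of 4 (median 0.95, percentile 98.3). Without CMK6 the median of the hypoblast list was -0.19. TMM scaling moved the median of all genes by -0.17.

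CMK9 was compared with CMK6 over 2 and 3 NextSeq cells, and the sex of the lines is not in the labels. X-linked genes differed from autosomal genes by 0.03 (CMK9 over CMK6, percentile 60.7), and inactivated genes split 52 to 55 (median -0.03). The signalling list was higher in CMK9 in 9 of 11 (median 0.98, percentile 99.9), with the ERK phosphatase DUSP6 at 354.2 against 52.1 CPM and ETV5 at 86.4 against 17.6 CPM. FAM43A was 103-fold higher, VIM stood at 1223 against 187.5 CPM and the secreted phosphoprotein SPP1 at 4123 against 447.7 CPM. Skeletal muscle actin ACTA1 was 28.4-fold lower and the immediate early gene EGR1 20.4-fold lower, and the stress list was lower in 7 of 9 (median -0.8, percentile 0.39). DNMT3B stood at 717.3 against 2303 CPM. On X, FHL1, at 62 CPM in CMK6, had no count in CMK9 (at least 49-fold lower), and TCEAL7, at 30.4 CPM in CMK9, had none in CMK6 (at least 24.7-fold higher). Half-widths of the counting intervals reached 29% here, no label could be compared with another, and 2 and 3 cells cannot show how far cells of a line vary.

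Within CMK9, SOLiD cells against NextSeq cells gave an X-linked difference of 0.48 over 298 X-linked and 7435 autosomal genes (percentile 100), with 117 at least 2-fold higher and 33 at least 2-fold lower. AMOT, an angiomotin gene on X, stood at 105.5 against 1.7 CPM. The autosomes ranged from -0.641 (chromosome 19) to 0.795 (chromosome 9), and X lay below chromosome 9 and above the other 19 autosomes, of which the highest stood at 0.255 (chromosome 1). Core pluripotency genes were lower in 9 of 10 (median -1.18, percentile 0.11), SPP1 was 25.8-fold lower and IDO2 93.2-fold lower. SOLiD cells of CMK9 against CMK6 gave an X-linked difference of 0.47 (percentile 100), which lay below chromosomes 9 (0.761) and 17 (0.587). Between NextSeq cells of CMK9 and CMK6, X stood at 0.03 and chromosome 17 at 0.429. With no CPM minimum the X-linked differences of SOLiD cells from NextSeq cells and from CMK6 were both 0.0. In the comparison of SOLiD cells with CMK6 the sequencer and the line cannot be told apart.

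XIST, the non-coding RNA that coats the inactive X, is not analysed here, since no gene of the tables carries its name. TSIX, its antisense partner, was read in its place with the limit that the strand used for counting is not given in the sources used here, so reads of the pair cannot be told apart. Its summed level was 14.2 CPM in E07 (interval 13.4 to 15), 15.7 CPM in E08 (14.6 to 16.9), 11.9 CPM in E13 (11.2 to 12.7) and 5.6 CPM in E16 (3.83 to 7.9). Cells differed widely: the median over cells was 3.83 CPM in E07, 1.97 CPM in E08, 0.63 CPM in E13 and 4.15 CPM in E16, so sums and medians order the stages differently. In CMK6 it was 0 CPM (interval 0 to 1.51). In CMK9 it was 8.43 CPM (5.15 to 13) in the 2 NextSeq cells, of which 1 stood at 15.7 and 1 at 0.86 CPM, and 0.08 CPM (0 to 0.43) in the 8 SOLiD cells. The sum of all 10 was 1.37 CPM (0.85 to 2.1), and 0.14 CPM without the highest cell, so no level of the line is read from it. In cells thinned to 200000 counts, a TSIX read was present in 52.4% of E07 cells (exact binomial interval 41.2% to 63.4%), 42.9% of E08 cells (28.8% to 57.8%) and 16 of 40 E13 cells (24.9% to 56.7%). Without thinning these shares were 75.0%, 57.1% and 52.5%. By class the sum (and the median over cells) was 11.4 (4.24) CPM in E07 epiblast-like, 21.6 (15.7) CPM in E07 hypoblast-like, 12.4 (0.86) CPM in E08 epiblast-like, 1.64 (0) CPM in E08 hypoblast-like and 31.4 (21.5) CPM in cluster 7. The highest E08 epiblast-like cell stood at 218.4 CPM, and 11 of the 22 had no read. The authors' RPM values for TSIX were above 0 in 12 of 195 cells, and the mean RPM was 0.03 in E07 and 0.1 in E08, so these levels rest on the count tables alone. They also depended on library labels: in the largest label of each group alone TSIX stood at 15.2 CPM in E07, 38 CPM in E08, 7.81 CPM in E13 and 10.8 CPM in E16, so no order of E13 and E16 is read from them.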

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

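The tests of library labels, of the range of the autosomes and of reads shared with LOC102139757 were chosen only after the results they bear on were seen.

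In the groups of 4 to 10 cells, E16 and CMK9, 2 cells stood far from the others of their group. TSIX stood at 15.69 CPM in replicate 10 of CMK9, a NextSeq cell of label MS173, and at 0.86 CPM in the next highest cell of the line. Replicate 4 of E16, also of label MS173, had 10277 genes with a read, and the next highest E16 cell had 7824. Both were found among 16 ends of 8 sets of values, and chance alone marks about 1 in 20 sets of normally distributed values. That rate does not hold for TSIX in CMK9, where 3 of 10 cells had a read and SOLiD and NextSeq cells were mixed.

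The X:A ratio was higher in E13 than in E08 epiblast-like cells. A trend with expression level that all genes share is argued against by the X-linked median at percentile 100 of matched autosomal lists. A difference confined to a few abundant genes is argued against by the 69.1% of X-linked genes above the autosomal median. A difference between library labels stays open. Summed over the 3 labels that held both stages the X-linked difference was 0.24, but this sum did not hold the label constant. These labels held 9 E08 and only 3 E13 cells, 1 in each label, too few to decide. They gave median ratios of 0.635 at E08 (6 cells) and 0.691 at E13 (1 cell) in MS130, and 0.619 (2 cells) and 0.931 (1 cell) in MS173, and MS132 gave 0.734 and 0.875 (1 cell each). The stage itself and differences between embryos, including their sex, also stay open as untested explanations.

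The X:A ratio was also higher in SOLiD than in NextSeq cells of CMK9. The X-linked median lay at percentile 100 of matched lists, which argues against a shared trend with expression level. Of the X-linked genes 66.4% lay above the autosomal median, which argues against a difference confined to a few abundant genes. The size of the ratio, which is one of means, did depend on the genes that entered. Over all 10 CMK9 cells its median was 1.477. It was 1.167 with genes chosen within CMK9 and 1.156 with no highest genes left out. A difference between the SOLiD and NextSeq libraries that also separates autosomes from each other stays open. X stood at 0.477, inside the autosomal range of -0.641 (chromosome 19) to 0.795 (chromosome 9), but chromosome 9 alone lay above it and the next autosome stood at 0.255, so the test does not decide. The sequencer and the library label cannot be told apart here. The labels place all these cells in 1 line but name no culture, and no biological explanation was tested.

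TSIX had counts in 121 cells, whereas its RPM was above 0 in 12. A candidate explanation is that the reads counted for TSIX came from the same transcripts as those of LOC102139757, a gene named in the files by its identifier alone. Of the 121 cells 119 also had a LOC102139757 count, and of the 55 cells without one 2 (3.6%) had a TSIX count. Counting on either strand and a different handling of overlapping genes in the RPM tables stay open, and no biological explanation was tested.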

How the results depend on the processing

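The settings that swapped the X-linked gene set, moved cluster 7, kept NextSeq cells alone, kept labels MS130 and MS173, with or without MS132, on both sides, dropped MS257 with MS273, or took the streak-led cluster at resolution 2 were chosen only after the results were seen, and so was the reading of TSIX. Here a value is the same when it moved by no more than the spread between cells, its counting interval or the spread of random lists, as fits it. For the log2 ratio of a gene the limit was 1, that is 2-fold, which is far wider than counting error. A value is reversed when its sign changed and the reported value lay outside the central 95% of matched lists, or for a gene at 2-fold or more. Of the recomputed X-linked differences 21 moved, 1 reversed and the others were the same, and all that moved or reversed are given below. Among those that moved, the values of E08 over E07 in epiblast-like cells and in all cells changed sign under some settings, and are not called reversed because the reported values lay inside that range. Over all genes taken by the rule 10390 of 11298 log2 ratios were the same, 849 moved and 59 reversed, and of list medians 2652 of 2903 were the same and 30 reversed. Of those printed in the text, 9 of 1828 log2 ratios and 22 of 1431 list medians reversed. For the reversals and shifts below the cause was not tested, except that fewer cells or genes enter where a label or a minimum is named. Cells could not be paired by animal, embryo or culture, which the labels do not name. Comparisons of stages restricted to library labels used only labels that held both, and where these were several, cells were summed over them.

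The X:A ratio depended on which genes and cells entered. With a minimum of 50 CPM it was 1.362 in E06, 0.887 in E08, 1.279 in E13, 1.368 in E16 and 1.097 in CMK6, and by class 0.794 in E07 epiblast-like, 0.84 in E07 cluster 6, 0.826 in E08 epiblast-like, 0.737 in E08 hypoblast-like, 1.123 in cluster 7, 1.289 in E13 and 1.368 in E16 epiblast-like cells. With X-linked genes of the fixed lists it was 1.308 in E06, 0.953 in E08 and 1.051 in CMK6, and by class 0.831 in E07 epiblast-like, 0.84 in E07 cluster 6, 0.849 in E08 epiblast-like, 0.812 in E08 hypoblast-like cells and 1.197 in cluster 7. With genes chosen within each group it was 0.627 in E09, 0.863 in CMK6, 1.167 in CMK9 and 0.718 in E08 hypoblast-like cells. With no highest genes left out it was 1.518 in E51, 0.894 in CMK6 and 1.156 in CMK9. The CMK9 values of 1.167 and 1.156 pool its SOLiD and NextSeq cells, whose pooled median was 1.477 in the main setting. A minimum of 1 CPM gave 0.788 in CMK6 and 0.687 in cluster 7. The median over genes gave 1.0 in CMK6, leaving out escaping and pseudoautosomal genes 0.86, and leaving out each of its cells 0.9 to 0.931. NextSeq cells alone gave 0.992 in CMK9, and hypoblast-like cells with cluster 7 gave 0.766 in E08.

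TSIX depended on the table used. As RPM its level was 0.0 in E06, E09 and E16, 0.03 in E07, 0.1 in E08, 0.02 in E13 and 0.07 in CMK9, and its share of cells 0.0% in E06, E09 and E16, 3.6% in E07, 8.2% in E08 and 7.5% in E13. In the largest library label alone it stood at 15.17 CPM in E07, 38 in E08, 7.81 in E13, 10.76 in E16 and 0.08 in CMK9 (8.43 in its NextSeq cells), with shares of 82.6% in E08 and 0.0% in CMK9. Shares of cells were 75.0% in E07 without thinning, and with at least 3 reads 34.5% in E07 and 0.0% in E06 and E51. Thinning to 100000 counts gave 0.0% in E06. CMK6 stayed at 0.0 CPM without each of its cells.

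X-linked differences were near 0 with no CPM minimum, which adds genes near 0 on both sides: 0.0 for E13 over E08 in epiblast-like cells, 0.01 for all cells, and 0.0 for SOLiD CMK9 over CMK6 and over NextSeq CMK9. For E13 over E08 in epiblast-like cells the value was 0.24 in sums over MS130, MS132 and MS173. For E08 over E07 in epiblast-like cells the value was 0.18 without MS257, 0.04 without MS130, 0.07 without MS219, -0.13 without MS273, 0.03 without MS257 and MS273, and -0.14 with a minimum of 50 CPM. In hypoblast-like cells it was -0.18 without MS252, -0.24 without MS219 and 0.13 with cluster 7 included. For all cells it was 0.23 without MS257, 0.13 without MS219 and -0.18 without MS273, and for all cells of E13 over E08 0.55 without MS273. For E16 over E13 in epiblast-like cells it was 0.14 with means of per-cell CPM at percentile 98.4 (0.16 for all cells, percentile 99.3), 0.15 without MS173 and 0.31 within MS173. Without each CMK6 cell it lay between -0.01 and 0.01 for the lines over E13, -0.04 and 0.09 for CMK9 NextSeq over CMK6, and 0.47 and 0.6 for CMK9 SOLiD over CMK6.

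Reversals of lists and genes came mostly from single labels. For E13 over E08 the streak list was -1.85 without MS127, -2.51 at resolution 2 and -2.96 in sums over MS130 and MS173, where IGFBP3 was -0.23. In sums over MS130, MS132 and MS173 the streak list was -1.55, and the list of inactivated X genes and PGK1 were -0.02. For E08 over E07 without MS219, the stress list and FOS were -0.79 in epiblast-like cells, and in hypoblast-like cells the post-implantation list was -0.66, the signalling list -0.7, VIM -0.3, ZIC2 -1.48, GSC -0.64 and LEFTY1 -1.05. With cluster 7 included, the escape list was 0.1 and TXLNG 0.54. For E16 over E13 the mesenchyme list was -0.01 with no minimum and -2.82 without MS173, as was VIM. The pre-implantation list was -0.04 without MS107, -0.42 in the streak-led cluster at resolution 2 and -1.58 within MS173. For the lines over E13 the hypoblast list was -0.83 with a minimum of 50 CPM, -0.03 with none and -0.19 without MS132, the label of CMK6. The signalling list was 0.18 with a minimum of 50 CPM, 0.09 without the E13 cells of MS127 and 0.05 without MS132, the trophoblast list -0.01 with no minimum and the stress list -0.09 without MS132. TMM scaling shifted the median of all genes by -0.11 in E08 over E07 hypoblast-like cells, and DESeq2 size factors by -0.11 in CMK9 SOLiD over CMK6. Leaving out a label that held all cells of a side, or fewer than 3 of them, was not run. For comparisons of classes, a resolution that gave identical cells on both sides or left fewer than 3 cells on one was not run either. Depth limited the lone E51 cell: the interval of a gene with no count reached 15.4 CPM there.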

Other observations

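The values below were chosen after they were seen, and no test was run on them. The 2 E13 cells that fell among the cells of the lines had mesenchyme transcripts and almost none of the pluripotency regulators. In their summed counts HAND1, a transcription factor of extraembryonic mesoderm, stood at 774.5 CPM (95% Poisson interval 746.9 to 802.9), against 1.1 CPM (0.9 to 1.3) in E13 epiblast-like cells. HAND2 stood at 291.5 CPM, GATA6 at 234.1 CPM and the transcription factor TBX20 at 167.0 CPM. POU5F1, the pluripotency factor, stood at 6.5 CPM (4.2 to 9.6) against 1052 CPM (1045 to 1059), and NANOG at 0.3 CPM against 650.2 CPM. Their X:A ratios were 0.854 and 0.813. HGF, VIM and COL3A1 helped to lead their cluster and are no result between clusters.

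The lone E51 cell had germ cell transcripts that were low or missing in the epiblast-like cells of E13. TFAP2C, a regulator of primordial germ cells, stood at 2424 CPM (2231 to 2630) against 5.8 CPM, and POU5F1 at 8658 CPM (8290 to 9039) against 1052 CPM. The germ cell genes DAZL and DDX4 stood at 112.7 CPM (74.2 to 163.9) and 75.1 CPM (44.5 to 118.7), against 7.4 and 8.3 CPM. DPPA5 had no count (interval up to 15.4 CPM), against 954.1 CPM. NANOS3 stood at 20.9 CPM (6.8 to 48.7), SOX17 at 8.3 CPM (1.0 to 30.1) and PRDM1 at 50.1 CPM (25.9 to 87.5). The lone E09 cell had NID2 at 4073 CPM (4008 to 4138) and GATA6 at 383.6 CPM (364.0 to 404.0) beside NANOG at 399.7 CPM (379.7 to 420.5), whereas NANOG stood at 0.5 CPM in E08 hypoblast-like cells. In the lone E06 cell NANOG stood at 2128 CPM (2003 to 2260), DNMT3L at 1430 CPM and DPPA3 at 726.7 CPM, with no NID2 count (interval up to 7.3 CPM).

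The sum of the 30 E07 cells of cluster 6 held transcripts of several lineages, and at resolution 2 the cluster split in a part of 14 cells led by GATA2, with 18 of 22 trophoblast markers detected, and a part of 17 cells with 9 of 22. KRT18 stood at 1836 CPM, APOA1 at 1149 CPM, GATA6 at 722.7 CPM and POU5F1 at 472.7 CPM, each with a read in all 30 cells. GATA2 had a read in 15 of the 30 cells and stood at 129.9 CPM.

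Chromosome 9 stood apart in the SOLiD cells of CMK9. The median log2 ratio of its 345 measured genes lay 0.795 above that of all autosomal genes against NextSeq cells of the same line, and 0.761 above it against CMK6 (342 genes). Between NextSeq cells of CMK9 and CMK6 the value was 0.05 (282 genes), and for the lines over E13 epiblast-like cells -0.228 (276 genes). Chromosome 19 lay at the other end in SOLiD cells, at -0.641 and -0.629. No explanation was tested for these values.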
